A study of Mus musculus with 2 samples.

How the data were processed

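The data were 10x Genomics 3-prime (v3 chemistry) single-cell libraries of sorted live CD45-positive cells, 1 from MC38 tumours of floxed Spp1 control mice and 1 from tumours of floxed mice with Lyz2-icre. Tumours had been digested with collagenase IV and DNase I, with an intended capture of 8000 cells and at least 20000 reads per cell on an Illumina NovaSeq, per the labels. Reads had been demultiplexed with bcl2fastq 5.0.1 and counted against mm10 with Cell Ranger, per the submitters' processing notes. The Cell Ranger version was 8.0.1 per the file headers, and the annotation release was not stated. The values used were the raw UMI counts (whole numbers per gene and barcode) deposited by the authors, for called cells only, with a lowest barcode total of 500 UMIs. Without the empty droplets, free RNA could not be estimated or removed. Of 55357 genes listed, 28475 had a UMI. Where several gene identifiers shared a symbol, the symbol was given to the one with the most UMIs. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand) and Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand) were located in the GENCODE vM21 annotation of mm10. The floxed exons were not stated, so a 3-prime tag could lie outside the deleted part and read RNA from a deleted copy.

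Cells with at least 300.0 genes, at least 500.0 UMIs and at most 15% mitochondrial UMIs were kept. This removed 430 of 9154 control barcodes (429 for mitochondrial share) and 29 of 13944 Lyz2-icre barcodes (22 for mitochondrial share). Total depth was 88529822 and 98275787 UMIs, with medians of 9075.5 and 6367.5 UMIs per barcode. Scrublet, run per library with an expected rate of 6%, called no doublet in either library (thresholds 0.658 and 0.464), so keeping the calls was the same as removing them. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen across both libraries, without Spp1, Lyz2, Xist, Y-linked, mitochondrial, ribosomal protein and receptor-segment genes. They were scaled and reduced to 30 principal components, a graph of 15 neighbours was built, and Leiden clustering was run at resolution 1 on both libraries together, with no batch correction. Lineages other than mononuclear phagocytes were clustered again with 20 components where they held at least 100 cells, at resolution 2 for T and NK cells and 1 for the rest.

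Clusters were named from 21 marker lists. A class needed 3 detected markers (at least 30 CPM and 3-fold over the lower quartile of clusters), a range-scaled mean score of at least 0.5 and a margin of 0.05 over the next class. Clusters outside the phagocytes whose C1q genes reached 25% of the macrophage-like level were set aside as mixed with macrophage RNA. These thresholds for naming were set while the clusters were being read, after the marker lists and before expression was compared. Clusters that met no class stayed unnamed. For each class and library UMIs were summed over cells and divided by the class total (CPM). Counts had exact Poisson intervals, ratios of CPM exact conditional binomial intervals and shares of cells Clopper-Pearson intervals, at 95%. A count of 0 was given only as a limit, from 3 counts for floors. Cells with a Xist UMI and no Y-linked UMI (4 genes) were taken as female, and the reverse as male.

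Named genes were the 12 highest and 12 lowest log2 ratios in macrophage-like and CD8 T-like cells, and 3 and 3 in other classes of at least 200.0 cells. They needed 50.0 CPM and 30.0 UMIs in the higher library, 1.5-fold with an interval clear of 1, and 0.2 of the highest class level, so that free RNA of another class was not named. Spp1, Lyz2, mitochondrial, ribosomal protein, haemoglobin, receptor-segment, Xist and Y-linked genes and unnamed gene models were left out of that ranking. Of each of 27 gene lists, members at 10 CPM or more were summarised by their median log2 ratio, compared with 10000 random lists drawn within 20 expression bins. Counting intervals of list medians came from 1000 Poisson draws. The 2 highest and 2 lowest members at 20 CPM or more were named, with no limit set by the highest class level. Symbols of 5 list and marker genes were changed to the names in the files. Cell states were read after drawing each cell down to 2000 UMIs, which left out 611 control and 1723 Lyz2-icre cells.

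Other settings chosen beforehand were no filter, a filter at 500 genes, 1000 UMIs and 10%, Leiden 0.5 and 2, 50 components, another seed, each library clustered alone, gates on UMIs, median-of-ratios scaling, mean of per-cell CPM, 1 and 20 CPM added, no filter on low genes and thinning. Median-of-ratios scaling moved the median by 0.01 in macrophage-like and -0.01 in CD8 T-like cells. Added after the data were seen were female cells only, male cells only, mixed CD8-led clusters counted in, the macrophage-like cluster with the largest excess of Lyz2-icre cells left out, and the highest Scrublet scores removed up to 0.8% per 1000 barcodes (639 and 1552 cells). These settings were run for 89 named genes, narrowed from 158 after the first run to those the text relies on.

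The steps were tested on simulated data, Poisson counts drawn from the real class means and depths with 200 genes changed by known folds. Intervals held the true ratio for 95.5% of 7763 genes in macrophage-like and 95.9% of 7967 genes in CD8 T-like cells. Changes of 1.5, 2 and 4-fold came back as median log2 0.53, 0.94 and 1.89 in macrophage-like cells and 0.55, 0.96 and 1.91 in CD8 T-like cells. Intervals left out 1 for every changed macrophage-like gene, and in CD8 T-like cells for 82.1% at 1.5-fold and 100% above. Unchanged lists fell within the central 95% in 94.5% and 98% of 200 draws. A few single-gene values and 1 cell state are not reported here. Tests of genotype, trajectories and ligand-receptor scores were left out, since 1 library per genotype gives no spread between animals. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.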

Results

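Single-cell RNA was measured in live CD45-positive cells sorted from MC38 tumours, a mouse colon carcinoma line, grown in floxed Spp1 control mice and in floxed mice that also carried the Lyz2-icre allele, which drives Cre recombinase in myeloid cells. There was 1 library per genotype and no replicate, so no difference between genotypes could be tested, and the number of mice behind each library was not stated. Intervals (95%) cover the counting of UMIs or cells and not the spread between mice. Those of UMI counts leave out the spread between cells as well, and are too narrow where the UMIs lie in few cells. The control library kept 8724 cells of 9154 barcodes, with 88047097 UMIs and a median of 9379.5 UMIs and 2892 genes per cell. The Lyz2-icre library kept 13915 cells of 13944 barcodes, with 98256831 UMIs and a median of 6374 UMIs and 2281 genes per cell. Expression is given in CPM, the UMIs of a gene scaled to the UMI total of its cell class, ratios are Lyz2-icre over control, and log2 ratios carry 5 CPM added to both libraries. Both libraries held cells with the female transcript Xist and cells with Y-linked transcripts, so animals of both sexes had been pooled. Values within a sex are given beside part of the results, and differences between the sexes were not tested.

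The first question was whether Spp1, which encodes the secreted phosphoprotein osteopontin, was lost from myeloid cells. In macrophage-like cells Spp1 stood at 867 CPM in the control library (860 to 875) and 2.40 CPM in the Lyz2-icre library (2.05 to 2.78), which was 362-fold lower (312 to 423, log2 -6.88). The UMIs behind these values numbered 50526 and 171. A second phagocyte cluster left unnamed, rich in the chitinase-like gene Chil3 and the arginase gene Arg1, showed the same loss, with Spp1 at 1074 and 2.60 CPM, or 412-fold lower (261 to 696). In neutrophil-like cells Spp1 counted 284 UMIs in the control library and 1 UMI in the Lyz2-icre library (ratio 0.0203, 0.000513 to 0.114), and in monocyte-like cells 68 UMIs and 1 UMI (ratio 0.0216, 0.00054 to 0.125). The thinned control share of monocyte-like cells was 8.26%, no higher than in classes taken as background below, so loss from monocytes themselves was not shown. Over all kept cells Spp1 was 730 CPM and 28.3 CPM (ratio 0.0387, 0.0373 to 0.0402, log2 -4.47). With every cell thinned to 2000 UMIs, 39.3% of control and 0.390% of Lyz2-icre macrophage-like cells held a Spp1 UMI. Without thinning these shares were 64.9% and 1.10%, at median depths of 9903 and 6741 UMIs.

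NK-like and CD8 T-like lymphocytes still carried Spp1 in the Lyz2-icre library. Natural killer (NK)-like cells stood at 750 CPM and 681 CPM (ratio 0.907, 0.831 to 0.990), and CD8 T-like cells at 234 CPM and 355 CPM (ratio 1.52, 1.31 to 1.76). After thinning, 36.1% of control and 28.9% of Lyz2-icre NK-like cells held a Spp1 UMI, at median depths of 6340 and 4002.5 UMIs. In the Lyz2-icre library the background share was 0.390%, that of macrophage-like cells. The control library had no such clean background, with 8.22% of migratory dendritic-like, 9.45% of unnamed T and 11.3% of cDC2-like cells holding a UMI, so part of its lymphocyte shares was free RNA. The matching shares of CD8 T-like cells were 20.9% and 16.8%. Without thinning 37.0% and 22.1% of CD8 T-like cells held a UMI, with 350 and 365 Spp1 UMIs. The UMIs of the Lyz2-icre library thus lay in fewer cells, and the CPM ratio of 1.52 is less certain than its interval. Regulatory T-like cells had 272 CPM and 215 CPM of Spp1 (ratio 0.792, 0.593 to 1.05), and after thinning 12.8% of 109 control and 5.26% of 57 Lyz2-icre cells held a UMI, the second value resting on 3 cells. Without thinning 23.3% of 133 control and 2.63% of 114 Lyz2-icre cells held a UMI, with 158 and 75 UMIs. The 215 CPM thus rested on few cells too. Unnamed T cells had thinned shares of 9.45% and 4.21%, and gamma-delta T-like cells counted 14 and 0 Spp1 UMIs (ratio under 0.660). Fibroblast-like cells had 254 CPM and 181 CPM (ratio 0.714, 0.626 to 0.813). Type 2 conventional dendritic cells (cDC2-like) lay between, with Spp1 at 59.7 CPM and 25.4 CPM (ratio 0.426, 0.280 to 0.631). Migratory dendritic-like cells counted 35 and 0 Spp1 UMIs, which put the ratio under 0.275. Free macrophage RNA in the droplets of the other classes was not subtracted, and there was more Spp1 to spread in the control library.

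**Figure D1:**
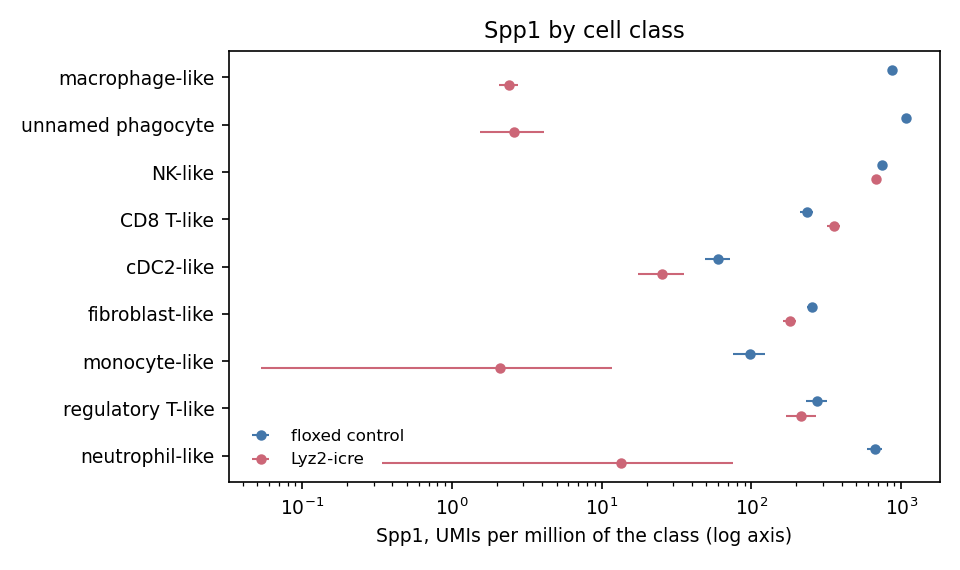
Spp1 in CPM (log axis) for each cell class with at least 100 control cells and a UMI in both libraries, control and Lyz2-icre, with exact Poisson 95% intervals as bars. Spp1 in macrophage-like cells stood at 867 and 2.40 CPM, while in NK-like cells it stood at 750 and 681 CPM.

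The second question was whether Lyz2, the myeloid lysozyme gene that carries the driver, differed as well. Lyz2 stood at 11293 CPM in control and 4011 CPM in Lyz2-icre macrophage-like cells, 2.82-fold lower (ratio 0.355, 0.354 to 0.357, log2 -1.49). The unnamed phagocyte class had Lyz2 at 14788 and 4846 CPM (ratio 0.328), and monocyte-like cells at 18022 and 8976 CPM (ratio 0.498, 0.481 to 0.516). After thinning, 99.0% of control and 78.5% of Lyz2-icre macrophage-like cells held a Lyz2 UMI. The log2 ratio of Lyz2 was -1.98 among female macrophage-like cells and -0.95 among male ones. Among Lyz2-icre macrophage-like cells thinned to 2000 UMIs, 33.0% of female cells (1672 of 5060, 31.7 to 34.4%) and 1.09% of male cells (19 of 1745, 0.657 to 1.70%) had no Lyz2 UMI. The control library had 1.30% of 3159 female and 0.616% of 1298 male macrophage-like cells without one. In the classes that do not make lysozyme, Lyz2 was taken as free myeloid RNA and was lower too, at 386 and 95.5 CPM in NK-like cells and 458 and 143 CPM in CD8 T-like cells.

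The third question was whether CD8 T cells made up more of the tumour leukocytes. They did not as a share of all kept cells, at 2.79% of the control library (243 cells, 2.45 to 3.15%) and 1.95% of the Lyz2-icre library (271 cells, 1.72 to 2.19%, ratio 0.699, 0.586 to 0.835). Among T cells, CD8 T-like cells made up 41.3% (243 of 589) and 45.2% (271 of 600, ratio 1.09, 0.917 to 1.31). Among cells outside the phagocyte classes and the mixed clusters, they made up 13.8% of 1759 and 16.2% of 1672 cells (ratio 1.17, 0.983 to 1.40). The share ratio of CD8 T-like cells was 0.637 (0.501 to 0.811) among female cells and 0.756 (0.526 to 1.09) among male cells. A count of cells with Cd8 and Cd3 UMIs at fixed depth, which also takes in cells inside mixed and unnamed T clusters, gave a ratio of 0.872 (0.748 to 1.02). A share in a sort is relative, and cell numbers per tumour were not analysed here.

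Macrophage-like cells filled the larger part of both libraries, at 64.2% (5598 cells) and 71.5% (9949 cells, ratio 1.11, 1.08 to 1.15). This ratio was 1.13 (1.08 to 1.18) among female and 1.01 (0.936 to 1.08) among male cells. The macrophage-like cluster with the largest excess of Lyz2-icre cells held 225 control and 1997 Lyz2-icre cells. Its cells were shallow, at median depths of 1895 and 2644 UMIs. Macrophage-like cells outside it made up a smaller part of all kept cells in the Lyz2-icre than in the control library. The larger share of macrophage-like cells in the Lyz2-icre library therefore rested on this cluster. Class shares with its cells also left out of the total were not computed. Unnamed phagocytes made up 6.797% and 8.77% (ratio 1.29, 1.17 to 1.43), a direction that turned with the clustering (0.192 at Leiden 0.5, 0.271 with another seed, 0.837 at Leiden 2). The phagocyte classes together, with that shallow cluster among them, made up 72.3% and 81.3% (ratio 1.12, 1.09 to 1.16). Neutrophil-like cells were scarcer in the Lyz2-icre library, at 1.95% (170 cells) and 0.460% (64 cells, ratio 0.236, 0.174 to 0.316). They remained so among cells outside the phagocyte classes (ratio 0.396, 0.292 to 0.531). Their median depths were 2356 UMIs in the control and 1052 UMIs in the Lyz2-icre library, where called barcodes began at 500 UMIs. Whether shallow neutrophil-like cells were missed when barcodes were called was not tested, so the lower share may in part reflect depth. The neutrophil-like ratio was 0.0934 among female and 1.47 (0.393 to 6.65) among male cells. Mast or basophil-like cells (ratio 0.320, 0.189 to 0.528), migratory dendritic-like cells (0.404, 0.313 to 0.519), gamma-delta T-like cells (0.475, 0.326 to 0.688, with 0.733 female and 0.0862 male) and regulatory T-like cells (0.537, 0.415 to 0.695) also had smaller shares. NK-like cells made up 2.96% and 1.94% (ratio 0.656, 0.551 to 0.781, with 0.606 female and 0.861 male), and T cells of every kind 6.75% and 4.31% (ratio 0.639, 0.569 to 0.717).

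Among the other dendritic cells, cDC2-like cells made up 2.54% and 1.62% (ratio 0.638, 0.528 to 0.772, with 0.568 female and 0.964 male) and cDC1-like cells 0.516% and 0.309% (ratio 0.599, 0.385 to 0.931). Plasmacytoid dendritic-like cells had a ratio of 0.761 (0.448 to 1.30). Monocyte-like cells made up 1.30% and 0.992% (ratio 0.766, 0.593 to 0.991), a direction that turned without a cell filter (1.31), at Leiden 0.5 (1.09), with another seed (1.40) and among male cells (1.42). Clusters mixed with macrophage RNA made up 7.58% and 6.73% (ratio 0.888), with 1.41 among male cells. B-like cells numbered 10 and 8, in a cluster led by Igha, Igkc and Jchain whose plasma cell score (0.940) was close to its B score (0.997). Fibroblast-like cells made up 1.98% and 1.73% (ratio 0.873, 0.715 to 1.07), and among cells outside the phagocyte classes 9.84% and 14.4% (ratio 1.47, 1.20 to 1.79). The absolute differences of the class shares, summed and multiplied by 0.5, came to 9.30 percentage points, with 9.81 among female and 4.59 among male cells.

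**Figure D2:**
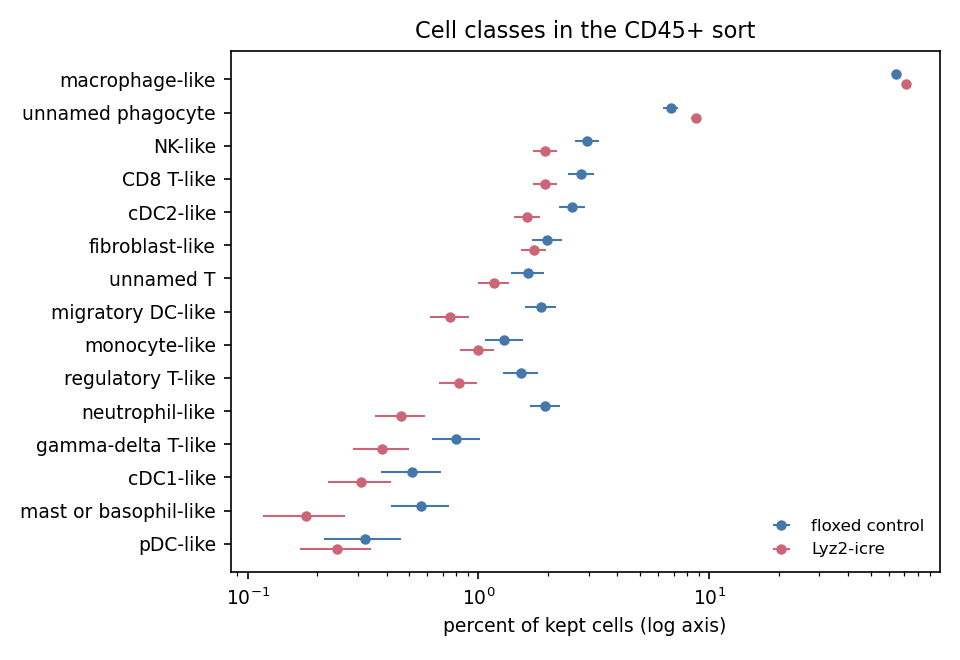
Percent of kept cells (log axis) in each cell class, control and Lyz2-icre, with Clopper-Pearson 95% intervals as bars. CD8 T-like cells made up 2.79% and 1.95%, neutrophil-like cells 1.95% and 0.460%, and macrophage-like cells 64.2% and 71.5%.

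The fourth question was how macrophage-like cells differed in expression. Among the genes lower in the Lyz2-icre library were Tnf (tumour necrosis factor) at 187 and 101 CPM (ratio 0.541, 0.525 to 0.557, log2 -0.85) and Il1a, an interleukin 1 gene, at 145 and 78.5 CPM (ratio 0.541, log2 -0.85). Nfkbia, the NF-kappaB inhibitor that NF-kappaB itself induces, stood at 1415 and 875 CPM (ratio 0.619, 0.612 to 0.625, log2 -0.69). The activin subunit Inhba was at 53.6 and 20.8 CPM (ratio 0.387, log2 -1.19), the matrix glycoprotein thrombospondin 1, Thbs1, at 597 and 310 CPM (ratio 0.520, 0.511 to 0.529, log2 -0.93), and the costimulatory ligand Tnfsf9 at 57.8 and 29.5 CPM (ratio 0.511, log2 -0.86). Also lower were the adaptor Stap1 (ratio 0.549), the phosphatase Dusp2 (0.568), the Fc receptor-like gene Fcrls (0.594), the EGFR inhibitor Errfi1 (0.596), the glutamine transporter Slc38a1 (0.601) and the microRNA locus Mir6236 (0.403). Stap1 (log2 -1.18 female, -0.03 male), Dusp2 (-1.18 and -0.13) and Fcrls (-0.91 and -0.15) differed little among male cells.

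Higher in Lyz2-icre macrophage-like cells were Retnla, a secreted marker of alternative activation, at 7.42 and 55.0 CPM (ratio 7.42, 6.72 to 8.21, log2 2.27), and the eosinophil attractant Ccl24 at 13.8 and 54.1 CPM (ratio 3.92, 3.63 to 4.24, log2 1.65). The monocyte and T-cell attractant Ccl8 stood at 180 and 500.4 CPM (ratio 2.77, 2.71 to 2.83, log2 1.45), the interferon-induced surface protein Ly6a at 256 and 491 CPM (ratio 1.92), and the arginine transporter Slc7a2 at 136 and 256 CPM (ratio 1.88, log2 0.89). The macrophage migration inhibitory factor Mif (ratio 1.66), the aminopeptidase Anpep (1.71) and the interferon-induced GTPase Iigp1 (1.61) completed the 8 genes that met the rule for being named as higher. Ccl8 held in both sexes (log2 1.495 female, 1.25 male). Retnla was 2.49 and 0.30, Ccl24 1.99 and -0.21, Slc7a2 1.73 and -0.85, and Anpep was -0.11 among male cells, so these 4 rested mainly on female cells.

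Gene lists fixed before the data were examined, as were the cell filters, the named-gene rule and most of the settings tried for robustness, were summarised by the median log2 ratio of their members and its percentile among 10000 random lists of like expression. Of 12 pro-inflammatory members 9 were lower (median -0.45, -0.49 to -0.41, percentile 0, -0.43 female, -0.57 male). Beside Tnf and Il1a these were led by Il1b, the interleukin 1 beta gene, at 1952 and 1298 CPM (ratio 0.665, log2 -0.59), while the costimulatory receptor Cd40 (log2 0.14) and the Fc receptor Fcgr1 (0.07) were not lower. Of 14 interferon-gamma response genes 13 were higher (median 0.27, 0.24 to 0.30, percentile 100, 0.48 female, 0.18 male). Irf1, an interferon regulatory factor, was at log2 0.11 and the guanylate-binding Gbp3 at -0.06. MHC class I genes were higher in 16 of 16 (median 0.18, 0.16 to 0.19, percentile 99.95, 0.24 female, 0.08 male), from the non-classical H2-Q7 (log2 0.35) and the peptide-loading Tapbp (0.33) to the proteasome subunit Psmb10 (0.06) and the peptidase Erap1 (0.02). MHC class II genes were higher in 9 of 9 (median 0.17, 0.17 to 0.20, percentile 98.7), from H2-Eb1 (0.28) and H2-DMa (0.28) to H2-DMb2 (0.14) and H2-Aa (0.06), but this median was 0.48 among female and -0.10 among male cells.

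Chemokine genes differed in direction. The T-cell attractants Cxcl9 (755 and 938 CPM, ratio 1.24, 1.23 to 1.26, log2 0.31) and Cxcl10 (409 and 511 CPM, ratio 1.25, log2 0.32) were slightly higher, whereas Ccl3 (396 and 178 CPM, ratio 0.449, log2 -1.13) and Ccl4 (888 and 426 CPM, ratio 0.480, log2 -1.05), which also attract T cells, were lower. Ccl3 was -1.51 among female and -0.18 among male cells, and Ccl4 -1.495 and 0.18. The T-cell chemokine list as a whole had 5 of 7 members higher (median 0.12, 0.09 to 0.15, percentile 87.9). The neutrophil attractant Cxcl3 was at 225 and 47.2 CPM (ratio 0.210, 0.202 to 0.218, log2 -2.14) and Cxcl1 at 517 and 328 CPM (ratio 0.634), in both sexes for Cxcl3 (-2.49 and -1.62). Ccl3, Ccl4 and Cxcl3 stood below 0.2 of the highest class level, so free RNA of another class was not excluded for them. With Ccl8 and Ccl6 (ratio 1.39) on the other side, the myeloid chemokine list had 4 of 9 higher (median -0.00, percentile 26.5, -0.21 female, -0.12 male).

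Alternative activation genes showed no common direction, with 8 of 14 higher (median 0.05, 0.01 to 0.07, percentile 80.2, 0.18 female, -0.01 male), the anti-inflammatory cytokine Il10 at 40.3 and 25.4 CPM (ratio 0.630, log2 -0.58) and the scavenger receptor Stab1 at log2 -0.39. Hypoxia and glycolysis genes were higher in 18 of 20 (median 0.24, 0.23 to 0.26, percentile 100), among them the mitophagy gene Bnip3 (ratio 1.47) and beside Mif, with the hexokinase Hk2 (log2 -0.02) and the growth factor Vegfa (-0.04) as the exceptions, but the list was 0.54 among female and -0.14 among male cells. Lipid-associated macrophage genes had 9 of 15 higher (median 0.12, percentile 98.1, 0.22 female, -0.07 male), from the fatty acid binder Fabp5 (438 and 816 CPM, ratio 1.86, log2 0.89) and the scavenger receptor Cd36 (0.44) to the lipid droplet coat Plin2 (-0.41) and the lysosomal lipase Lipa (-0.15). Fabp5 stood below 0.2 of the highest class level, so free RNA of another class was not excluded for it. Genes described with Spp1-high tumour macrophages had 7 of 13 higher (median 0.08, percentile 87.0), led by Fabp5 and the elastase Mmp12 (log2 0.48) and closed by Thbs1 and Cxcl3, with 0.51 among female and -0.73 among male cells.

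Of 10 inhibitory genes 7 were lower (median -0.12, percentile 1.64), with Il10 and the receptor Lilrb4a (117 and 74.4 CPM, ratio 0.635, log2 -0.62) lowest, and Pdcd1lg2, a ligand of PD-1, higher at 12.96 and 31.9 CPM (ratio 2.46, 2.26 to 2.67, log2 1.04; 1.75 female, -0.30 male). The other PD-1 ligand, Cd274, was at 92.2 and 106 CPM (log2 0.19, with 0.57 female and -0.33 male). Osteopontin receptor genes had 5 of 7 lower (median -0.12, percentile 4.68, -0.13 female, 0.02 male), with Cd44 at log2 -0.15, the integrin chain Itga9 at -0.23, Itgb1 at 0.10 and Itga5 at 0.03. Matrix genes were split 6 and 6 (median 0.04, percentile 73.4, 0.15 female, -0.21 male), with Mmp12 and the protease inhibitor Timp2 (0.41) against the protease Mmp14 (-0.22) and the urokinase receptor Plaur (-0.21). Complement genes were split 5 and 5 (median 0.03, percentile 56.7, -0.02 female, 0.19 male), with the properdin gene Cfp at 0.13. Type I interferon genes had 9 of 14 higher (median 0.08, percentile 98.3, -0.04 female, 0.17 male), with the nucleic acid sensor Zbp1 (0.32) and Ifit1 (0.31) against the antiviral genes Rsad2 (-0.48) and Ifit2 (-0.36).

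Cell cycle genes had 14 of 21 higher (median 0.07, percentile 96.4), with the cyclin Ccnb1 (log2 0.31) and the ubiquitin enzyme Ube2c (0.19) against the proliferation marker Mki67 (-0.33) and the replication clamp Pcna (-0.14), but -0.28 among female and 0.61 among male cells. Dissociation and heat-shock genes had 9 of 14 lower (median -0.08, percentile 2.16, -0.19 female, 0.03 male), with the early genes Jun (-0.55) and Ier2 (-0.32) against Hsph1 (0.16) and Hspa1b (0.14). Mitochondrially encoded genes had 10 of 11 lower (median -0.55, percentile 0), from mt-Nd3 (-1.27) and mt-Nd2 (-1.03) to mt-Co3 (0.21), with the median mitochondrial share of kept cells at 1.64% and 0.796%. Nuclear-encoded oxidative phosphorylation genes had 15 of 18 higher (median 0.13, percentile 98.9), with Uqcr10 (0.30) and Cox8a (0.26) highest and Ndufa4 (-0.40) lowest. The median of 7905 measured genes was -0.01.

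**Figure D3:**
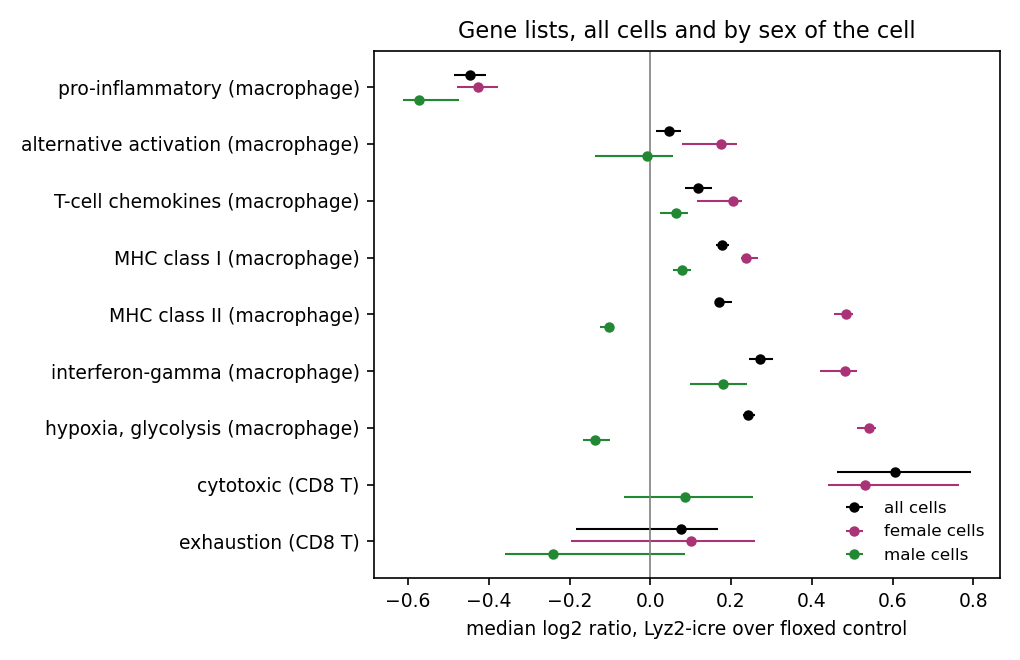
Median log2 ratio (Lyz2-icre over control) of 9 gene lists in all, female and male cells, with counting intervals as bars. Pro-inflammatory genes in macrophage-like cells stood at -0.45, -0.43 and -0.57, while hypoxia and glycolysis genes stood at 0.54 among female and -0.14 among male cells.

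The fifth question was whether the CD8 T cells differed in effector genes. Granzyme B, the killing protease encoded by Gzmb, stood at 522 CPM in control and 1050 CPM in Lyz2-icre CD8 T-like cells (ratio 2.01, 1.83 to 2.21). The related granzymes Gzmf (592 and 1161 CPM, ratio 1.96, 1.79 to 2.14), Gzme (122 and 299 CPM, ratio 2.44, 2.03 to 2.95), Gzmd (ratio 2.06) and Gzmc (128 and 548 CPM, ratio 4.29, 3.64 to 5.09) were higher as well. So were the chemokines Ccl1 (85.5 and 387 CPM, ratio 4.53, 3.70 to 5.57), Ccl3 (177 and 500.01 CPM, ratio 2.83, 2.43 to 3.29) and Ccl4 (876 and 1643 CPM, ratio 1.88, 1.74 to 2.02). Further genes named as higher were the lectin-like receptor chain Klrd1 (793 and 1494 CPM, ratio 1.88, 1.74 to 2.03), the inhibitory receptor Klra5 (ratio 2.25), the interferon-induced Ifitm1 (2.12), the chaperone Hspa1a (3.08) and the repressor Zbtb32 (1.999). Gzmc did not meet the rule for named genes. It stood below 0.2 of the highest class level, so free RNA of another class was not excluded for it.

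The granzymes differed by sex. Gzmb was log2 1.44 among female and -0.05 among male CD8 T-like cells, Gzmf 2.49 and -0.66, Gzme 2.96 and -0.92, and Gzmd 3.999 and -2.02, whereas Gzmc (3.83 and 0.59, male 0.22 to 0.98) and Gzma (3.16 and 2.16, male 0.957 to 3.23) were higher in both. Klra5 was 1.23 and 0.11. Ccl1 (2.21 and 1.82), Klrd1 (0.93 and 1.003), Ccl4 (0.72 and 1.20) and Ifitm1 (1.03 and 1.60) held in both. Gzmd, Gzme and Gzmf, like Hspa1a and its copy and the Klra genes, are near-identical copies, so UMIs could not be assigned to each of them with certainty.

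Lower in Lyz2-icre CD8 T-like cells was Itga4, the integrin chain that binds VCAM-1 and osteopontin, at 206 and 80.7 CPM (ratio 0.391, 0.303 to 0.50004, log2 -1.30). The muscle-type enolase Eno3 stood at 79.5 and 27.2 CPM (ratio 0.343), the vesicle transport gene Sft2d2 at 100.2 and 37.0 CPM (ratio 0.369) and the insulin receptor substrate Irs2 at 68.1 and 28.2 CPM (ratio 0.414). Also lower were the long noncoding RNA Lncpint (50.8 and 20.4 CPM), the mitotic kinesin Kif20b (55.4 and 23.3 CPM), the methyltransferase subunit Ash2l (64.1 and 29.2 CPM), the DNA end-resection gene Rbbp8 (91.5 and 42.8 CPM) and the endosomal gene Acap2 (56.1 and 26.3 CPM). The methyltransferase-like Pcmtd1 (87.5 and 42.8 CPM), Fam172a (76.1 and 37.0 CPM, ratio 0.486) and the microRNA locus Mir6236 (199.7 and 54.5 CPM, ratio 0.273) closed the named genes. Rbbp8 was -1.68 among female and -0.22 among male cells, Itga4 -1.40 and -0.59 (-1.31 to 0.03) and Eno3 -1.396 and -0.64 (-1.71 to 0.24), so the male intervals of Itga4 and Eno3 held 0. Mir6236 was lower in each of the classes examined by the rule that named any gene.

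Of 16 cytotoxic effector genes 13 were higher in CD8 T-like cells (median 0.61, 0.46 to 0.80, percentile 100), with 0.53 among female and 0.09 (-0.07 to 0.25) among male cells. Granzyme A (Gzma; 4.01 and 42.8 CPM, ratio 10.7, 4.54 to 30.7, log2 2.41) and Gzmc (2.06) led, though so low a level of Gzma did not exclude RNA of NK-like cells. Interferon gamma (Ifng; 578 and 899 CPM, ratio 1.55, 1.42 to 1.71), Tnf (ratio 1.57, 1.06 to 2.33) and perforin (Prf1; 1.32) were higher too. The chemokine Ccl5 was lower at 1470 and 825 CPM (ratio 0.560, 0.517 to 0.606, log2 -0.83), and the death ligand Fasl had a ratio of 0.837. Exhaustion genes had 7 of 13 higher (median 0.08, -0.18 to 0.17, percentile 79.3, 0.10 female, -0.24 male). Tox, the transcription factor that fixes exhaustion, was at 219 and 111 CPM (ratio 0.506, 0.405 to 0.628, log2 -0.95) and the nuclear receptor Nr4a2 at log2 -0.63, while the signalling regulator Rgs16 (0.49) and the receptor Cd160 (0.45) were higher. PD-1 (Pdcd1) had a ratio of 0.789 and TIM-3 (Havcr2) 1.28.

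Osteopontin receptor genes were lower in 5 of 5 (median -0.31, -0.77 to -0.13, percentile 2.07, -0.15 female, -0.33 male), led by Itga4 and the alpha-v integrin Itgav (335 and 207 CPM, ratio 0.619, 0.525 to 0.728, log2 -0.68; -0.78 female, -0.32 male, -0.76 to 0.10), with Cd44 at 204 and 186 CPM and Itgb1 at 239 and 202 CPM. Hypoxia and glycolysis genes had 16 of 19 higher (median 0.17, 0.13 to 0.28, percentile 98.7, 0.36 female, -0.13 male), with Bnip3 (ratio 1.60) and Ankrd37, a HIF target (1.67), highest. T-cell receptor signalling genes had 8 of 12 higher (median 0.16, percentile 97.8, 0.30 female, 0.05 male), with the costimulator Icos (ratio 1.31) and the factor Irf4 (39.4 and 56.4 CPM) against Nr4a3 (116 and 91.4 CPM) and Myc (43.4 and 33.1 CPM). Residency and homing genes had 9 of 14 higher (median 0.12, percentile 94.3), with the integrin Itgal (ratio 1.28) and the chemokine receptor Ccr2 (83.5 and 109 CPM) against Runx3 (ratio 0.852). Naive and memory genes had 4 of 9 higher (median -0.15, percentile 20.7, 0.36 female, -0.52 male), with the survival gene Bcl2 (ratio 0.813) and Klf2 (62.1 and 43.8 CPM) against the lymphotoxin chain Ltb (1.14) and the cytokine receptor Il7r (1.08).

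In CD8 T-like cells interferon-gamma response genes had 5 of 14 higher (median -0.19, -0.37 to 0.02, percentile 14.5, -0.10 female, 0.16 male) and type I interferon genes 4 of 8 (median -0.03, percentile 65.8, 0.18 female, -0.04 male). Cell cycle genes had 11 of 21 higher (median 0.02, percentile 67.6, -0.30 female, 0.34 male) and stress genes 8 of 14 (median 0.05, percentile 68.6, -0.03 female, 0.54 male). Mitochondrially encoded genes were lower in 10 of 11 (median -0.56, percentile 0) and nuclear-encoded oxidative phosphorylation genes higher in 15 of 18 (median 0.21, percentile 99.55). The median of 8447 measured genes was -0.07.

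By cell, and with each cell thinned to 2000 UMIs, 31.7% of 230 control CD8 T-like cells (25.8 to 38.2%) and 50.4% of 226 Lyz2-icre cells (43.7 to 57.1%) held a Gzmb UMI (ratio 1.59, 1.17 to 2.16). The background share in macrophage-like cells was 0.326% and 0.562%, and unthinned shares in CD8 T-like cells were 42.8% and 57.6%, at median depths of 5037 and 3365 UMIs. Cycling cells, with a UMI of Mki67 or Top2a, made up 30.0% and 36.3% (ratio 1.21, 0.867 to 1.69), but 44.9% and 39.9% without thinning. Of thinned macrophage-like cells 24.5% and 25.2% held such a UMI, and free RNA was not subtracted. Cells with both Pdcd1 and Havcr2 made up 10.9% and 6.19% (ratio 0.570, 0.274 to 1.14), and stem-like cells with Tcf7 1.74% and 1.33%. A cluster marked by Gzmf, Ifng and Ccl1 held 47 control and 185 Lyz2-icre CD8 T-like cells, whereas a cluster marked by Pdcd1 and Tox held 159 and 34.

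The last question was whether the remaining classes differed in the same direction. Expression in these classes was not rerun under the other settings or within a sex. Changes of sign between the sexes, as for Slc7a2 and MHC class II genes in macrophage-like cells, were therefore not examined in them. The unnamed phagocytes had the T-cell attractant Cxcl9 (233 and 516 CPM, ratio 2.22, 2.08 to 2.36), Slc7a2 (ratio 2.05, 1.84 to 2.28) and Ly6i (ratio 2.05) higher, and Mir6236 (ratio 0.360) and the proteoglycan gene Vcan (130 and 50.9 CPM, ratio 0.392, 0.344 to 0.446) lower. They had 14 of 14 interferon-gamma genes (median 0.58, percentile 100), 16 of 16 MHC class I genes (0.30, percentile 100) and 9 of 9 MHC class II genes (0.37, percentile 99.995) higher, with pro-inflammatory genes lower (-0.34, percentile 0). The chemokine Ccl5 was at 74.3 and 177 CPM, in a T-cell chemokine list at 0.40 (percentile 99.99). Type I interferon (0.27, percentile 99.96) and alternative activation genes (0.16, percentile 99.2) stood above 0 in unnamed phagocytes and myeloid chemokines below (-0.23, percentile 0.195). Their other medians, some of them opposite in sign to those of macrophage-like cells, were 0.11 for hypoxia, -0.11 for lipid, 0.02 for Spp1-high, 0.02 for complement, -0.14 for matrix, -0.17 for inhibitory, -0.17 for osteopontin receptor, -0.13 for cell cycle, 0.04 for stress, -0.67 for mitochondrially encoded and 0.08 for oxidative phosphorylation genes.

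In NK-like cells Gzma, the granzyme that was scarce in CD8 T-like cells, stood at 1269 and 2509 CPM (ratio 1.98, 1.87 to 2.09), with Ifitm1 (ratio 2.04) and the mitochondrial gene Cmc2 (1.95) also higher. The interferon-induced chemokine Cxcl10 (106 and 40.7 CPM, ratio 0.382), the centriolar gene Pcm1 (0.424) and Mir6236 (0.380) were lower. Their interferon-gamma (-0.29, percentile 1.59) and type I interferon lists (-0.34, percentile 3.56) were below 0, unlike in phagocytes, while cell cycle genes were at 0.13 (99.4), cytotoxic genes at 0.07, exhaustion genes at -0.17, osteopontin receptors at -0.25 and mitochondrially encoded genes at -0.47. In cDC2-like cells the surface proteins Ly6i (19.4 and 55.4 CPM, ratio 2.86) and Ly6a (ratio 2.21) and the chaperone Hspa1a (2.19) were higher, and the adhesion protein Flrt3 (110 and 41.6 CPM, ratio 0.379), the mitotic gene Cenpf (0.385) and Mir6236 (0.291) lower.

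Regulatory T-like cells had 10 of 15 effector genes lower (median -0.11, -0.22 to 0.02, percentile 5.03), with the checkpoint receptor Ctla4 at 1653 and 1175 CPM (ratio 0.711). In neutrophil-like cells, of which the Lyz2-icre library held 64, the mature circulating list had 10 of 12 lower (median -1.27, -1.72 to -0.80, percentile 0), where the median of every measured gene was 0.37. A cluster led by Retnlg, with Lcn2 and Ngp, held 34 control cells and 1 Lyz2-icre cell, and the mix of clusters was not separated from this list. The granule genes Ngp (473 CPM), Ltf (155 CPM) and Camp (93.7 CPM) of the control library counted no UMI in the other, and the siderophore binder Lcn2 was at 3919 and 839 CPM. Tumour neutrophil genes had 6 of 14 higher (median -0.12, percentile 4.48).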

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

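Before the values below were read, tests were set for doublets with macrophages, depth, free RNA, NK cells in the class, the mix of clusters and animals of 1 sex; the tests of mixed clusters counted in, of dilution by phagocytes and of dissociation stress were chosen only after the result was seen.

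CD8 T-like cells made up a smaller share of the Lyz2-icre library (2.79% and 1.95%), opposite in direction to the greater CD8 T-cell infiltration named in the title of the study. A share in a sort is relative, and cell numbers per tumour were not analysed here. The ratio was 1.09 (0.917 to 1.31) among T cells and 1.17 (0.983 to 1.40) among cells outside the phagocyte classes and mixed clusters. Loss of CD8 T cells into doublets with macrophages stays open. A gate on Cd8 and Cd3 UMIs at fixed depth gave a ratio of 0.872 (0.748 to 1.02), with an interval that holds 1. That gate also takes in unnamed T cells, such as a cluster with Cd8a at 201 and 358 CPM, so its ratio is not particular to doublets. Clusters mixed with macrophage RNA made up 7.58% of control and 6.73% of Lyz2-icre cells. Counting the mixed CD8-led clusters back in gave 0.765 (0.666 to 0.880), so those clusters did not account for all of it. Mixed clusters without Cd8 and Cd3 genes among their leading genes were left out of that count. A mixed T-cell cluster left out held 69 and 108 cells, with Cd8a at 88.1 and 114 CPM, so not every cluster set aside was covered. CD8 T-like cells over the other cells outside the phagocyte classes and mixed clusters came to 1.21 (1.01 to 1.44). That interval leaves out 1, so the classes were not diluted alike by phagocytes. The other cells include neutrophil-like cells (170 and 64), whose lower share may in part reflect depth. A smaller reduction of CD8 T-like cells than of other lymphocytes was therefore not shown. How far the larger share of phagocytes lowered the CD8 T-like share was not settled. Whether animals of 1 sex made the difference cannot be told apart, as the larger ratio of the sexes was 0.756 (0.526 to 1.09) and too few male cells were counted.

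Cytotoxic effector genes stood higher in Lyz2-icre CD8 T-like cells (median 0.61). The mix of clusters in this class differed between the libraries. A cluster marked by Gzmf, Ifng and Ccl1 held 47 control and 185 Lyz2-icre cells, and 1 marked by Pdcd1 and Tox held 159 and 34. Mitochondrially encoded genes, a sign of RNA quality, stood at -0.56 in these cells. The bearing of the cluster mix or of RNA quality on the list was not tested. With every cell thinned the list median was 0.57 (0.40 to 0.75). Thinning leaves the expected CPM of each cell unchanged, so this test could not decide on depth. Free RNA of NK cells did not explain the list, since granzymes and perforin in macrophage-like cells came to 1.25% of the gap between the CD8 T-like cells of the libraries (1831 and 3697 CPM). NK cells counted in the class did not either, with Ncr1 and Klrb1c at 1.56% of the NK level where 9.85% would be needed. Animals of 1 sex cannot be told apart from a genotype effect, because the median nearer to 0, among male cells, was 0.0858 (-0.07 to 0.25) and its interval holds 0. Gzmd (3.999 female, -2.02 male), Gzme (2.96 and -0.92) and Gzmf (2.49 and -0.66) took opposite signs and may belong to particular animals. Gzma (3.16 and 2.16, male 0.957 to 3.23) and Gzmc (3.83 and 0.59, male 0.22 to 0.98) were higher in both sexes. However, Gzma was too low in CD8 T-like cells to exclude RNA of NK-like cells. Gzmc stood below 0.2 of the highest class level, the limit set against free RNA of another class.

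Macrophage-like cells of the Lyz2-icre library had lower pro-inflammatory genes (median -0.45) and higher interferon-gamma response genes (0.27), beside lower mitochondrially encoded genes (-0.55), a sign of RNA quality whose bearing on either list was not tested. For the first, another mix of macrophage clusters is a possible explanation, because the mean of the medians within 8 clusters was -0.21 (range -0.48 to 0.19), smaller in size than the -0.22 set beforehand as 0.5 of the pooled median. The mean was not weighted by cells, and the cluster at 0.19 (0.02 to 0.39) held 225 control cells. Genes of the lists were not left out when clusters were built, which can itself shrink medians within clusters. For the second, the mix cannot be told apart from a shift within clusters, since the mean was 0.26 but clusters ranged from -0.14 to 0.51. Animals of 1 sex did not explain either list, with -0.43 (-0.48 to -0.38) and 0.18 (0.10 to 0.24) as the medians nearer to 0. Less stress in dissociation cannot be told apart for the pro-inflammatory genes, as the stress list was near 0 at -0.0828 but 9 of its 14 members, too few to rule it out, stood above the bound.

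In macrophage-like cells the following log2 ratios took opposite signs among female and male cells, a difference between the sexes that was not tested. Secreted and surface genes were Ccl24 (1.99 and -0.21), Ccl4 (-1.50 and 0.18), Ccl6 (0.80 and -0.24), Il10 (-0.85 and 0.28), Pdcd1lg2 (1.75 and -0.30), Vegfa (0.51 and -0.82), Mmp12 (0.91 and -0.32), Stab1 (-0.72 and 0.44) and H2-DMb2 (0.63 and -0.56). Metabolic genes were Slc7a2 (1.73 and -0.85), Fabp5 (1.55 and -0.20) and Bnip3 (1.03 and -0.14). Lists were MHC class II (0.48 and -0.10), hypoxia and glycolysis (0.54 and -0.14), the Spp1-high tumour macrophage list (0.51 and -0.73), matrix (0.15 and -0.21) and cell cycle (-0.28 and 0.61). In CD8 T-like cells the cytokine receptor Il7r was 0.76 and -0.56, and the cell cycle list -0.30 and 0.34. The rule that picks these was narrowed after a first run gave about 40 pairs, to opposite signs with both intervals clear of 0 and, for genes, at least 1 log2 between the sexes.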

How the results depend on the processing

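Every alternative for animals of 1 sex, for the highest Scrublet scores, for mixed CD8-led clusters and for the excess cluster was chosen only after the result was seen, and the others were planned. For animals of 1 sex that result was the pooled one, and the tests above were set before the values by sex were read. No paired analysis was possible because each genotype had 1 library and no animal was shared between them. Log2 ratios or list medians are given unless a share ratio is named.

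The planned settings left 122 of 148 share values, 217 of 256 list values and 503 of 623 gene values close to the first ones, and the added settings 40 of 57, 61 of 115 and 164 of 317. The planned counts include the setting that kept doublet calls, which matched by construction because no doublet was called. Values that reversed direction numbered 7, 1 and 2 over planned settings and 3, 11 and 25 over added ones. CD8 T-like share ratios ran from 0.699, the value reported above, to 0.872 over planned settings, and none was lower. Among T cells they ran from 1.09, again the value reported above, to 1.34. Neutrophil-like share ratios ran from 0.133 to 0.295, NK-like from 0.656 to 0.677 and migratory dendritic-like from 0.369 to 0.431. The cytotoxic list ran from 0.51 to 0.64, the pro-inflammatory list from -0.47 to -0.31 and the interferon-gamma list from 0.22 to 0.31. In CD8 T-like cells the cell cycle list ran from -0.0311 to 0.41 and the osteopontin receptor list from -0.39 to -0.15. The Gzmb state, 18.7 points apart at 2000 UMIs, was 11.3 points apart at 1000 UMIs and 14.8 points without thinning.

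Share ratios that moved were, for monocyte-like cells, 1.31 without a filter, 1.09 at Leiden 0.5, 1.40 with another seed and 1.42 among male cells. Those of unnamed phagocytes were 0.192 at Leiden 0.5, 0.837 at Leiden 2, 0.994 with 50 components and 0.271 with another seed. Macrophage-like cells came to 1.16 at Leiden 2, 1.18 with another seed, 1.01 among male cells and 1.03 by the gate. CD8 T-like cells came to 1.34 of T cells with each library clustered alone and to 0.872 of kept cells by the gate. The share of cells that would have to change class (0.5 of the summed absolute differences of class shares) was 10.8 points with libraries alone, 13.4 with another seed and 4.59 among male cells. Male cells gave 1.41 for mixed clusters and 1.47 for neutrophil-like cells (0.393 to 6.65). The cause was not tested for any of these.

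Median-of-ratios scaling gave Lyz2 -1.50 and MHC class II 0.16. Adding 1 CPM gave Spp1 -7.999, and adding 20 CPM gave Spp1 -5.31, pro-inflammatory genes -0.31 and interferon-gamma genes 0.22. Without a filter on low genes the Spp1-high list was -0.0255. The mean of per-cell CPM gave Spp1 -6.68, Fcgr1 -0.00421, alternative activation 0.00559, T-cell chemokines 0.16, MHC class I 0.15, MHC class II 0.22 and interferon-gamma genes 0.31. Thinning gave Lyz2 -1.47, Fcgr1 -0.0204 and MHC class II 0.22. The stricter filter gave Lyz2 -1.50 and MHC class II 0.15. With the highest Scrublet scores removed Lyz2 was -1.50, alternative activation 0.0804 and T-cell chemokines 0.15. Without the excess cluster Spp1 was -7.15 and MHC class II 0.16. The cause was not tested for the values that turned.

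Among female macrophage-like cells Spp1 was -6.80, Lyz2 -1.98, Fcgr1 -0.0644, Vegfa 0.51, alternative activation 0.18, T-cell chemokines 0.21, MHC class I 0.24, MHC class II 0.48, type I interferon -0.0359, interferon-gamma 0.48 and cell cycle -0.28. Among male ones Spp1 was -7.16, Lyz2 -0.95, Ccl24 -0.21, Slc7a2 -0.85, Anpep -0.11, Bnip3 -0.14, Ccl4 0.18, Ccl6 -0.24, Cd274 -0.33, Cd40 -0.22, Fabp5 -0.20, H2-Aa -0.37, H2-DMa -0.0415, H2-DMb2 -0.56, H2-Eb1 -0.0795, Il10 0.28, Irf1 -0.0957, Mmp12 -0.32, Pdcd1lg2 -0.30 and Stab1 0.44. Male list medians were pro-inflammatory -0.57, alternative activation -0.00786, T-cell chemokines 0.0637, MHC class I 0.0776, MHC class II -0.10, interferon-gamma 0.18, hypoxia -0.14, lipid -0.0671, Spp1-high -0.73, matrix -0.21, osteopontin receptors 0.0207 and stress 0.0331. Male CD8 T-like cells gave Gzme -0.92, Gzmd -2.02, Gzmb -0.0492, Gzmf -0.66, Ltb -0.0884, hypoxia -0.13, cytotoxic 0.0858 and exhaustion -0.24. Without thinning the cycling state differed by -5.00 points and the Pdcd1 and Havcr2 state by -14.8 points. The cause was not tested for these.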

Other observations

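The tests of the fibroblast-like cells and of an even drop of Lyz2 below were chosen only after the result was seen, and the bounds for Lyz2 were set after its ratio by sex was known.

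Fibroblast-like cells, 173 in the control and 241 in the Lyz2-icre library, carried collagen III (Col3a1) at 9768 and 8821 CPM, the proteoglycan gene Dcn at 1520 and 1385 CPM and the matrix gene Sparc at 2464 and 2443 CPM. Of the epithelial markers, the keratins of simple epithelia were near absent, with Krt8 at 2 and 2 UMIs, Krt18 at 9 and 4, Krt19 at 2 and 1 and Krt7 at 14 and 12 UMIs in the whole libraries, and the adhesion gene Epcam at 0.434 and 0 CPM in this class. The tight junction gene Tjp1 stood at 93.3 and 83.7 CPM there, against 4.95 and 4.66 CPM over all cells, and the basal keratin Krt14 was among the leading genes of a fibroblast-like cluster of 53 cells and of an unnamed non-immune cluster of 61 cells. Epcam counted 753 and 491 UMIs over the whole libraries and marked cDC2-like clusters, where it is also made. The endothelial genes Emcn and Cldn5 had 0 UMIs, the haemoglobin gene Hba-a1 3 and 3 UMIs, and the platelet gene Ppbp 177 and 105 UMIs.

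Sex-linked RNA showed the pooling of animals. Xist stood at 749 and 626 CPM and the Y-linked genes together at 67.2 and 63.3 CPM. Female cells made up 59.6% and 55.8% of the libraries, male cells 20.6% and 17.6%, and cells with both 7.62% and 6.92%, where free mixing of RNA would give 19.0% and 15.4%. Cells with neither made up 12.2% and 19.6%. Each genotype therefore held animals of both sexes, with called cells of each sex in like proportion, while the proportion of animals was not known. Calls of sex needed a UMI, and Xist was far more abundant than the Y-linked genes. A male cell with a free Xist UMI and no Y-linked UMI would be called female, and calls depend on depth. Values within a sex carry this limit, which was not measured.

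Most of the fibroblast-like cells may be cells of the injected tumour line and not of the mice. Of those thinned, 93.8% (90.9 to 96.0%) had neither Xist nor a Y-linked UMI, against 21.1% to 75.0% in 10 other classes, of which the shallow neutrophil-like cells were the highest. A line from a female mouse that lost its inactive X, or a male line that lost its Y, would look this way, while host fibroblasts would carry the RNA of their sex, as did 1 cluster of the class led by Mgp and Postn (Xist at 634 and 813 CPM, neither in 2 of 9 and 3 of 12 thinned cells). That cluster also held leukocyte RNA (C1qa at 1002 and 287 CPM, Cd8a at 71.9 and 189 CPM), so its Xist may not be that of fibroblasts. Against a source in the tumour line, the sort for CD45 should remove cells of the line, as it should fibroblasts. The line is also a carcinoma and Krt7, Krt8, Krt18 and Krt19 were near 0, although Krt14 and Tjp1 were present, so a largely mesenchymal state of the line would have to be assumed. Genotyping reads over strain variants or the floxed Spp1 alleles in sorted cells could settle it.

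Female Lyz2-icre animals may have had no intact Lyz2 copy in part, since the driver sits in Lyz2 and 2 driver alleles would end its expression. An even drop in each female cell was excluded, since male counts lowered evenly to the female mean would leave 4.47% of cells without a Lyz2 UMI, against 33.0% (31.7 to 34.4%) of female cells. If some animals lacked it and others had 1 copy, female cells with Lyz2 would match male ones. Their mean Lyz2 count over that of male cells with a UMI was 0.722 (8.96 and 12.4 UMIs), short of the 0.8 set for this mixture, with free Lyz2 RNA in the droplets blurring the lower end, so a mixture of animals cannot be told apart from a mixture of cells within animals. Female cells with 1, 2 and 3 UMIs made up 9.27%, 4.39% and 4.11%. Animals with 1 and with 2 driver alleles, kept apart, could show whether loss of lysozyme itself added to the macrophage differences.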
